A study of Homo sapiens with 6 samples.

How the data were processed

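Biotinylated cRNA from laser-captured Capan1 cells was hybridised to Illumina expression BeadChips, 6 arrays in all, 3 of Capan1 grown with PS1 stellate cells and 3 of Capan1 alone. Per the labels' protocols, RNA was extracted with a micro-scale column kit and labelled with an Ambion MessageAmp kit. The deposited table gives a probe intensity and a detection p-value for each array, per the file headers, and its intensity values are not normalized between arrays. BeadStudio and GenomeStudio 2011.1 are named in the submitters' processing notes, and the steps between the scanner and the table are not given in the sources used here. The detection p-value of the deposited table moves in steps of 0.0013, which corresponds to 770 negative control probes. The authors' deposited value table for the same arrays holds intensity on a linear scale that is not centred, with the same rank order of probes as the signal of the same array (Spearman rho = 1), and the columns share a distribution, as quantile normalization gives, within 3.11% of the mean quantiles. Its medians were 122.93, 122.96 and 122.90 in replicates 1, 2 and 3 with stellate cells and 122.94, 122.94 and 122.93 alone. It was used as an alternative.

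Samples were grouped by their titles and source names. A further label, which names PS1 as the line the cells were exposed to, stands on all 6 samples and so conflicts with the titles of the 3 samples of Capan1 alone. What each change means rests on the titles being right. No source used here says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. From the signals, background was corrected with limma's normexp method with negative control levels taken from the detection p-values, an offset of 16 was added, and the values were quantile normalized and set on the log2 scale. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 18165 of 47228. Group means were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. An exact permutation test of 3 against 3 cannot give a p under 0.1 and was not used for single genes. A probe not detected on any array of a group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected level and the probe's own. Figures were drawn with matplotlib 3.10.9.

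Genes were named through the platform's annotation table and a table of human RefSeq genes of the assembly GRCh38.p14, which was used for names alone, so no coordinates are given. Of the tested probes 13986 had 1 gene symbol, 3 several and 4176 none, and the 10781 genes were each represented by the probe with the highest mean over the 6 arrays. Of the 730 probes past the threshold 91 had no single gene name. Among the named genes the probes disagreed in direction for TGM2, CD44, HSPE1 and GAPDH. In calls, 1 of 2 probes passed for CAV1, KIF23 and PTTG1, and 1 of 3 for RARRES1.

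Before the data were examined, 34 gene lists were fixed. They covered stellate and fibroblast, epithelial and duct, mesenchymal, blood and immune cell and housekeeping genes, and the WNT, hedgehog, NOTCH, TGF-beta, NF-kappa-B, JAK and STAT3, EGFR and ERK, retinoic acid, p53 and NRF2 pathways. They also covered both parts of the cell cycle, hypoxia, glycolysis, interferon and antigen presentation genes, matrix proteases, integrins and laminins, secretory, classical, basal-like and squamous genes, the unfolded protein response, heat shock proteins, immediate early genes, cholesterol synthesis, metallothioneins, ribosomal proteins and the respiratory chain. The 33 lists with at least 5 measured genes were tested with camera, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. With the preset correlation 11 lists passed, and with a correlation estimated for each list 1 did, the secretory list. Counts adjusted over the list alone use the same fit with the adjustment run within the list. Median, mean and test differed in sign in the WNT, matrix protease, glycolysis, metallothionein and p53 lists.

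The genes named in the text were set by a rule fixed at the same time. It takes the 12 genes higher and the 12 lower with the largest change among those past the threshold whose groups do not overlap, up to 4 members with the smallest p from each list past its threshold, and ACTB and GAPDH. From the stellate, epithelial, WNT, and G2 and M phase lists it adds the 3 members with the smallest p and the 3 with the highest mean. Genes named outside it are said to have been chosen after their values were seen. The alternatives tried were other background corrections, offsets, normalizations, filters on dim probes, variance models, thresholds and set tests, the authors' value table, array weights, the replicate number as a block, and each array left out in turn. Array brightness as a covariate, and the member counts of the lists without single arrays or under other settings, were added after seeing the data.

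The fit was tested on simulated data with 3 arrays against 3, the noise of the 6 arrays and 17274 probes tested. Of 50 probes changed by each size, 0% were recovered at a log2 change of 0.5, 16% at 1, 56% at 1.5 and 60% at 2, with 2 calls among 17081 unchanged probes. Background noise was added to values whose spread already held it, and fewer probes were changed than the 730 called in the data, so recovery may be understated. In the same simulated comparison 1 list, shifted by 0.5 after normalization, was found and 0 of 30 unshifted lists were called. The simulated noise was drawn independently for each gene, whereas the estimated correlation was 0.81 in the G2 and M phase list. The simulation therefore cannot show how often lists of correlated genes are called falsely.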

Results

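Capan1, a well differentiated human pancreatic cancer cell line, was grown on top of gels of type I collagen and Matrigel, either alone or with PS1 cells, a pancreatic stellate cell line, embedded in the gel. Stellate cells are the fibroblast-like cells of the pancreas that lay down the fibrous stroma of pancreatic tumours. The gels were lifted onto grids after 24 hours and fed from below, and the cancer cell layer was taken by laser microdissection from frozen sections of gels harvested on day 10. Illumina BeadChips measured RNA from 3 samples of Capan1 with stellate cells and 3 of Capan1 alone. The array carried 47228 probes, of which 18235, 19602 and 16325 were detected in replicates 1, 2 and 3 with stellate cells and 19206, 17785 and 18194 in replicates 1, 2 and 3 alone. The mean deposited signal per array lay between 273 and 494 intensity units. The comparison asks how expression in the cancer cells differs when stellate cells are in the gel.

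Capan1 cells with stellate cells in the gel expressed more of a list of mucin and secretory genes than Capan1 cells alone, and most genes of G2 and M phase were lower. SAA2, an acute-phase serum amyloid A gene read by probe ILMN_1728262, was 7.31-fold higher with stellate cells, at a log2 intensity of 9.07 ± 0.38 against 6.20 ± 0.51 alone (SD, n = 3 arrays each, limma adjusted p = 0.00054). DKK1, a secreted inhibitor of WNT signalling read by probe ILMN_1773337, was 7.04-fold lower, at 7.17 ± 0.78 with stellate cells against 9.99 ± 0.21 alone (SD, n = 3, limma adjusted p = 0.00094). Of 32 measured genes of G2 and M phase, 27 fell, and of 14 measured mucin and secretory genes, 9 rose (camera adjusted p = 0.282 and 0.0485 with an estimated correlation). Among 18165 probes tested, 366 were higher and 364 lower with stellate cells at a limma adjusted p under 0.05, which stood for 303 and 271 named genes. At an unadjusted limma p under 0.05 there were 3331 probes. In 23.6% of the tested probes the values of the groups did not overlap, against an average of 10% over all splits of 3 against 3. Probes move together across arrays, so a single split can lie far from that average. The share in the other splits was not computed.

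The 12 genes with the largest rise, after SAA2, were HLA-DPA1, SAA1, S100A8, RNASE1, LGALS4, FCGBP, PIGR, PSCA, TFF3, BPIFB1 and HSD17B2. HLA-DPA1, an MHC class II alpha chain, had a log2 change of 2.71 ± 0.28 (SE) and was detected on 3 arrays with stellate cells and on 2 alone. SAA1 had a log2 change of 2.51 ± 0.27, and S100A8, a subunit of the calcium-binding protein calprotectin, one of 2.50 ± 0.22. SAA1 and SAA2 are near-identical copies, as are parts of the MHC class II genes, so the share of each gene in its probe's signal is uncertain. RNASE1, a secreted ribonuclease, was 5.61-fold higher. LGALS4, which encodes galectin-4, was detected on no array of Capan1 alone and on all 3 with stellate cells, where it was at least 4.19-fold higher. FCGBP, a protein of mucus, was 5.51-fold higher, and PIGR, the receptor that carries polymeric immunoglobulins across epithelia, was 4.51-fold higher. HSD17B2, which oxidises oestradiol and testosterone, was 3.92-fold higher. Over these 12 genes the limma adjusted p ran from 0.00051 for S100A8 to 0.0250 for BPIFB1. The size of a change in dim genes depends on the background correction: without it the log2 change was 1.88 for SAA2, 1.38 for HLA-DPA1, 2.18 for SAA1, 1.12 for LGALS4 and 1.92 for PIGR.

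The 12 genes with the largest fall, after DKK1, were TM4SF19, TNFAIP3, CDCA3, NAV3, GPAT3, CAV1, MMP10, WNT7B, TNFRSF11B, MAOB and EPHB6. TNFAIP3, which encodes the NF-kappa-B inhibitor A20, had a log2 change of -1.98 ± 0.21 (SE). CAV1, the main coat protein of caveolae, had one of -1.94 ± 0.22, and WNT7B, a WNT ligand, one of -1.93 ± 0.26. TM4SF19, NAV3 and TNFRSF11B, the last of which encodes the decoy receptor osteoprotegerin, were detected on no array with stellate cells and on all 3 alone. They were at least 2.50-fold, 2.77-fold and 3.02-fold lower. MMP10, the matrix protease stromelysin-2, was 3.82-fold lower and was detected on 2 of the 3 arrays with stellate cells, as were MAOB and EPHB6. Over these 12 genes the limma adjusted p ran from 0.00089 for TNFAIP3 to 0.0176 for MMP10. Without background correction the log2 change was -2.17 for DKK1, -1.36 for TNFAIP3, -0.84 for TM4SF19, -0.82 for TNFRSF11B, -0.82 for EPHB6 and -0.80 for NAV3. The bounds given above therefore hold only with that correction. The housekeeping genes ACTB and GAPDH had log2 changes of -0.08 ± 0.16 and 0.11 ± 0.15, with adjusted p of 0.835 and 0.747. That of ACTB turned positive without replicate 3 with stellate cells and with array weights.

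**Figure D1:**
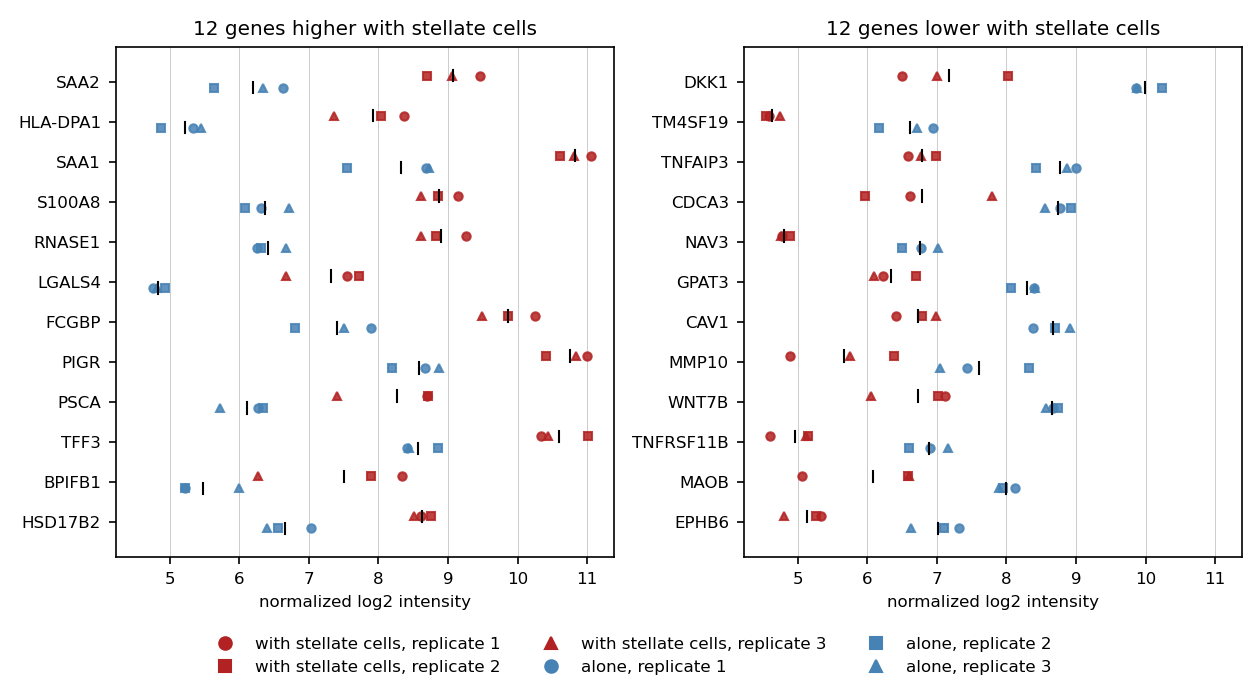
Normalized log2 intensity (x axis) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) with stellate cells, one symbol per array and a black line at each group's mean (n = 3 per group). In every gene shown the values of the groups are separate, with SAA2 at 9.07 on average with stellate cells and 6.20 alone, and DKK1 at 7.17 and 9.99.

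All 32 measured genes of G2 and M phase had values below 0 for the change with stellate cells, and 27 of them fell at an adjusted p over all genes under 0.05, or 32 adjusted over the list alone. The median log2 change of the list was -1.20 (camera adjusted p = 9.5e-30 with the preset correlation, and adjusted p = 0.282 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, was 2.69-fold lower, TOP2A, the topoisomerase that untangles replicated DNA, 2.76-fold lower, and KIF23, a motor protein of cytokinesis, 3.14-fold lower. UBE2C and TPX2 had log2 changes of -1.40 ± 0.19 and -1.31 ± 0.19 (SE). PTTG1 and CDC20 had values of -0.91 ± 0.24 and -0.96 ± 0.25 that did not pass (adjusted p = 0.0597 and 0.0531). A dimmer probe of PTTG1, 1 of its 2, did pass in the same direction. Of 28 genes of DNA replication 3 fell, or 9 adjusted over the list alone: RRM2 and RRM1, the subunits of ribonucleotide reductase, at -1.80 ± 0.22 and -0.79 ± 0.20, and UHRF1, which maintains DNA methylation, at -0.83 ± 0.14. This list had a median of -0.44 (camera adjusted p = 1.5e-06, and adjusted p = 0.597 with an estimated correlation), which ran from -0.67 to -0.28 when 1 array was left out.

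Replicate 3 with stellate cells stood apart in these genes. The mean of the G2 and M phase list, each gene centred over the 6 arrays, was -0.77, -1.07 and -0.01 in replicates 1, 2 and 3 with stellate cells and 0.55, 0.72 and 0.58 alone. For DNA replication, replicate 3 with stellate cells was at 0.24, inside the range of the arrays alone, 0.16 to 0.27. The same array had the highest 28S ribosomal RNA signal, with a log2 intensity of 12.85 against 5.97 to 8.32 on the others, and the fewest probes detected. Without it 32 genes of G2 and M phase and 20 of DNA replication fell. Leaving out replicates 1 or 2 with stellate cells or replicates 1, 2 or 3 alone left 8, 12, 9, 5 and 8 genes of G2 and M phase past the threshold. Without the intensity trend 11 passed, and with array brightness as a covariate, a setting chosen after seeing the data, 8 did. Without replicate 1 with stellate cells, or without replicate 3 alone, 1 gene of DNA replication passed.

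**Figure D2:**
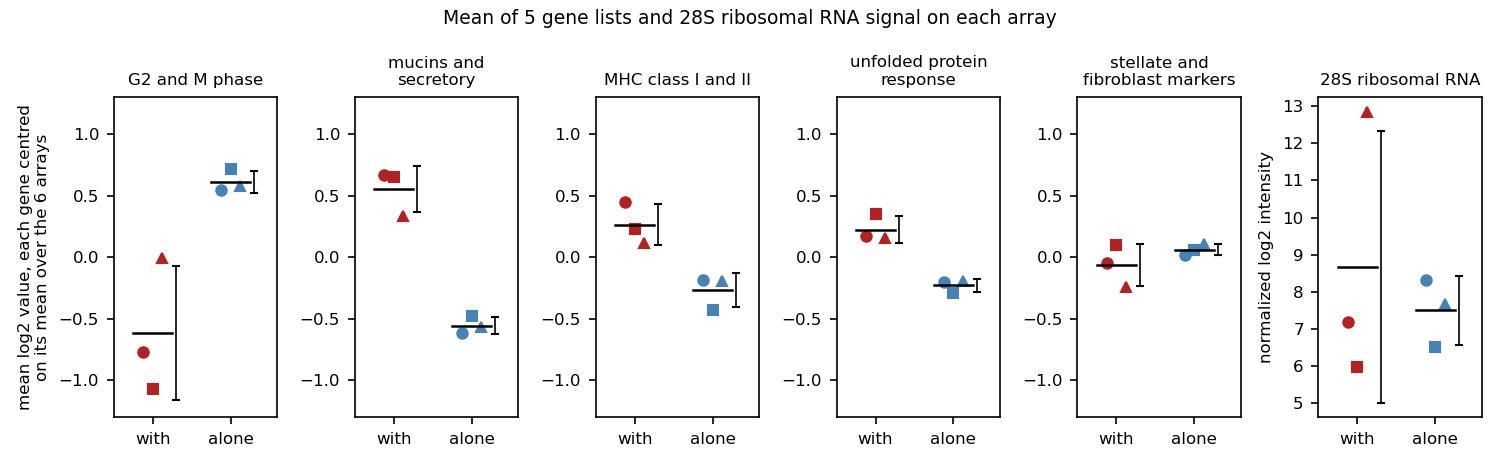
Mean log2 value of 5 gene lists on each array, each gene centred on its mean over the 6 arrays, and normalized log2 intensity of 28S ribosomal RNA (far right), with one symbol per array (circle, square and triangle for replicates 1, 2 and 3), lines at the group means and bars of 1 SD (n = 3). Replicate 3 with stellate cells lies at -0.01 for G2 and M phase, between the other arrays with stellate cells and those alone, and at 12.85 for 28S ribosomal RNA.

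Mucin and secretory genes rose as a list. All 14 measured genes had values above 0, and 9 rose at an adjusted p over all genes, or 12 adjusted over the list alone, with a median log2 change of 0.94 (camera adjusted p = 1.1e-13, and adjusted p = 0.0485 with an estimated correlation). MUC1, a membrane mucin, was 2.29-fold higher at a log2 intensity of 13.10 ± 0.22 with stellate cells against 11.90 ± 0.05 alone (SD, n = 3). AGR2, a protein disulphide isomerase needed for mucin folding, was 2.08-fold higher, and TFF3, a trefoil peptide secreted with mucins, 4.07-fold higher. Of 16 genes of the classical pancreatic cancer subtype, a gland-like expression class of these tumours, 8 rose, or 12 adjusted over the list alone, with a median of 0.87 (camera adjusted p = 2.9e-12, and adjusted p = 0.120 with an estimated correlation). These lists are not independent: AGR2, AGR3, LYZ, TFF1, TFF2, TFF3, REG4 and ST6GALNAC1 are in both as fixed. Of the 8 that rose 4, AGR2, TFF1, TFF2 and TFF3, are among them. MUC1 is also in the epithelial and duct list. AGR3, LYZ, TFF1 and TFF2 were named after their values were seen, and REG4 and ST6GALNAC1 are named as list members only. PLA2G10, a secreted phospholipase, and PRR15L had log2 changes of 1.47 ± 0.18 and 1.39 ± 0.18 (SE). The list of the basal-like subtype, with 13 genes measured, had 0 past the threshold, also 0 adjusted over the list alone, and a median of 0.12 (camera adjusted p = 0.896), but 4 were higher and 2 lower without replicate 3 with stellate cells. The centred mean of the secretory list was 0.34 in replicate 3 with stellate cells, the array with the high ribosomal RNA signal, 0.67 and 0.65 in replicates 1 and 2, and -0.62 to -0.48 alone. Leaving that array out gave 12 genes higher in each of the secretory and classical lists. Without replicate 3 alone 5 secretory genes passed, as with array brightness as a covariate.

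Of 16 measured genes of antigen presentation by MHC class I and II 5 rose, or 6 adjusted over the list alone. The 5 were HLA-DPA1, HLA-DMA, HLA-DMB, HLA-DRA and CD74, the invariant chain that escorts class II molecules, and the other was TAPBP, which helps to load peptides on class I molecules, at 0.54 ± 0.20 (SE, adjusted p = 0.161 over all genes). HLA-DMB and TAPBP were named after their values were seen, and no test compared the classes. HLA-DMA, CD74 and HLA-DRA were 2.94-fold, 2.73-fold and 2.48-fold higher. The median of the whole list was 0.17 (camera adjusted p = 0.0022, and adjusted p = 0.437 with an estimated correlation), and leaving out 1 array moved it between 0.091 and 0.29. The list's centred mean was 0.12 in replicate 3 with stellate cells, 0.45 and 0.23 in replicates 1 and 2, and -0.42 to -0.18 alone, and without that replicate 3 the list had 7 genes higher. Of 30 interferon-stimulated genes 3 rose, or 5 rose and 2 fell adjusted over the list alone, and the list did not pass (median 0.04, camera adjusted p = 0.503). Leaving out replicate 1 with stellate cells or any array alone left 0 of the 3.

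The list of the endoplasmic reticulum stress response had values above 0 in all 20 measured genes and a median log2 change of 0.43. It passed with the preset correlation (camera adjusted p = 6.5e-06) but not with an estimated one (camera adjusted p = 0.282). With the preset, 4 of the 10 splits of the arrays into 3 and 3, the real one included, gave at least the real 11 lists. A list call that rests on the preset is therefore weak evidence of a shift. DNAJB9, HSPA5 and CRELD2, chaperones or chaperone partners of the endoplasmic reticulum, rose by 1.81-fold, 1.84-fold and 1.58-fold, and 6 genes passed adjusted over the list alone. Without replicate 3 with stellate cells 8 of its genes passed, and without any other array 0 did. The heat shock list, cytosolic and mitochondrial chaperones for the most part, had a median of -0.44 (camera adjusted p = 0.00011, and adjusted p = 0.282 with an estimated correlation). In it CHORDC1, a partner of HSP90, fell by 1.03 ± 0.19 on the log2 scale (SE), while HSPB1 had a value of 0.53 ± 0.14 (adjusted p = 0.0515). Of its 16 genes 1 fell, or 5 fell and 1 rose adjusted over the list alone. Without replicate 3 with stellate cells 9 fell and 1 rose, and without replicates 1 or 2 with stellate cells or replicates 2 or 3 alone 0 passed. That array's centred mean was 0.15 for the stress response, against 0.17 and 0.35 in the other arrays with stellate cells, and 0.01 for heat shock, against -0.29 in both.

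The list of hypoxia targets had a median of 0.37 (camera adjusted p = 0.0022, and adjusted p = 0.437 with an estimated correlation). Of its 19 genes 0 passed singly, or 2 adjusted over the list alone, and 5 passed without replicate 3 with stellate cells. Its median ran from 0.17 to 0.45 when 1 array was left out. CA12, a carbonic anhydrase, and BNIP3L, a mitophagy receptor, had values of 0.64 ± 0.18 and 0.78 ± 0.22 (SE). The retinoic acid list had a median of 0.39 (camera adjusted p = 0.0011, and adjusted p = 0.282 with an estimated correlation). Of its 12 genes 2 rose, or 4 adjusted over the list alone. These were RARRES1 and PLAAT4, at 3.50-fold and 2.87-fold, and TGM2 had a value of 1.04 ± 0.27 (adjusted p = 0.0526) with 1 of its 3 probes in that direction. Without replicate 3 with stellate cells 5 passed but the median fell to 0.24, the lowest of the fits that leave out 1 array, against 0.41 as the highest, and without replicates 2 or 3 alone 1 passed. In the squamous and cornified envelope list 4 of 15 genes rose, or 5 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0077, and adjusted p = 0.282 with an estimated correlation). Its median moved between 0.20 and 0.50 when 1 array was left out. Without replicate 3 with stellate cells 6 rose. The 4 were S100A8, S100A9 and S100P, calcium-binding proteins, and PI3, the elastase inhibitor elafin, and no keratin was among them. The keratin KRT23 and SLPI were added without replicate 3 with stellate cells, both named after their values were seen. The epithelial and duct list had a median of 0.20 (camera adjusted p = 0.0077, and adjusted p = 0.437 with an estimated correlation), and 4 of 23 genes rose, also 4 adjusted over the list alone. Leaving out replicate 1 with stellate cells took the median to 0.057, and leaving out replicate 3 with stellate cells to 0.39. MUC1, ELF3, an epithelial transcription factor, and CLDN3, a tight junction protein, were 2.29-fold, 2.10-fold and 2.01-fold higher, and PROM1 1.87-fold higher. KRT19 and EPCAM, with log2 intensities of 13.62 ± 0.17 and 12.61 ± 0.27 with stellate cells (SD, n = 3), had changes of 0.03 and -0.11. Those changes turned sign without replicate 2 with stellate cells, and that of KRT19 also without replicate 1 alone and with array brightness as a covariate. Of the epithelial list 8 genes passed without replicate 3 with stellate cells, and 2 without replicate 1 with stellate cells or replicates 1 or 2 alone. That array's centred mean was the lowest of those with stellate cells in these lists, at 0.03 for hypoxia, 0.06 for retinoic acid, 0.03 for the squamous list and -0.03 for the epithelial list.

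Of 32 markers of stellate cells and fibroblasts 9 were measured in the captured cancer layer, 0 rose and 1 fell, or 1 rose and 2 fell adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.637). COL6A1, a chain of type VI collagen, fell by 1.31 ± 0.28 on the log2 scale (SE), a call that was lost without replicate 1 with stellate cells or without any of the arrays alone. ACTA2 and TAGLN, genes of contractile fibres, had values of -1.04 ± 0.27 and 0.87 ± 0.24 (adjusted p = 0.0526 and 0.0674), and TAGLN was detected on no array alone and on all 3 with stellate cells. TAGLN passed with cyclic loess, median scaling, array weights or no intensity trend, and without background correction its value was 0.32. When replicate 3 with stellate cells was left out, 2 of the 9 markers were higher, TAGLN and COL6A3, and 2 lower, COL6A1 and ACTA2. COL6A3, another chain of type VI collagen, was named after its values were seen. COL1A2 and LUM were detected on no array, COL3A1, SPARC and POSTN on no array with stellate cells, and DCN on 2 arrays with stellate cells and on none alone, a set of genes picked after the values were seen. Of 9 measured mesenchymal transition genes 1 fell, or 2 adjusted over the list alone (median -0.07, camera adjusted p = 0.306). It was SNAI2, a repressor of epithelial genes, at -1.51 ± 0.23, named after its values were seen. Blood and immune cell markers, with 7 genes measured, had 0 past the threshold, or 1 higher and 1 lower adjusted over the list alone, and a median of 0.21 (camera adjusted p = 0.505). In the fit that leaves out replicate 3 with stellate cells 2 mesenchymal genes were lower, and 2 blood and immune markers were higher and 1 lower.

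**Figure D3:**
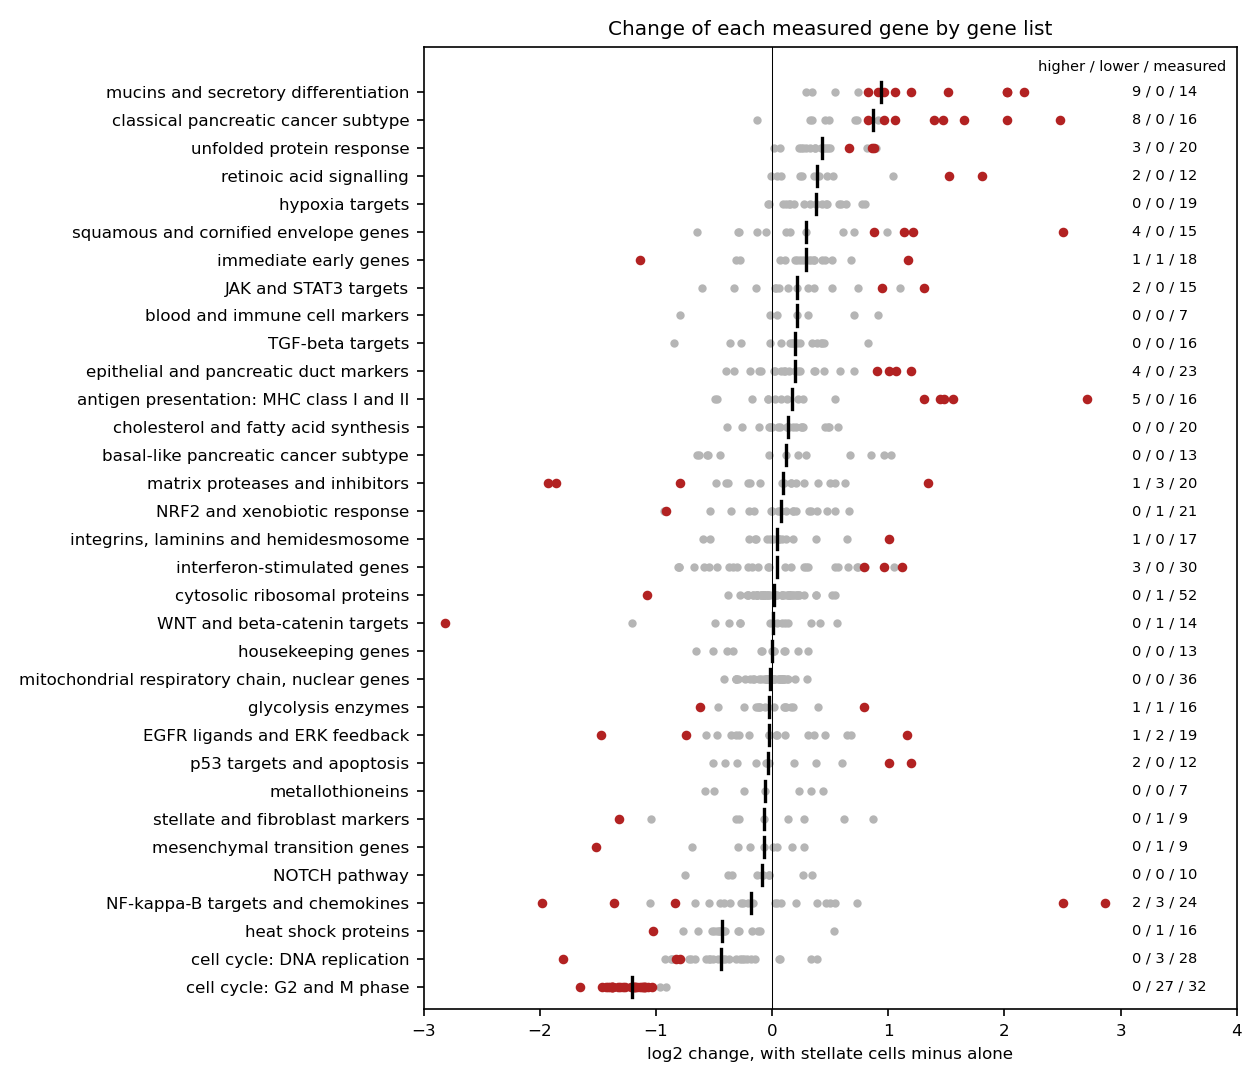
Log2 change with stellate cells minus alone (x axis) of each measured gene in the gene lists with at least 5 measured genes, with red points for genes at a limma adjusted p under 0.05, grey points for the others and black lines at the medians. The G2 and M phase list has its median at -1.20 with 27 of 32 genes lower, and the secretory list at 0.94 with 9 of 14 higher. Numbers at the right give the genes higher, lower and measured.

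Of 24 NF-kappa-B targets and chemokines 2 rose, SAA1 and SAA2, and 3 fell, TNFAIP3, RELB and IL32, or 4 and 6 adjusted over the list alone (median -0.18, camera adjusted p = 0.521). The log2 changes of RELB, an NF-kappa-B subunit, and IL32, a cytokine, were -1.36 ± 0.27 and -0.84 ± 0.18 (SE). Of 15 JAK and STAT3 targets 2 rose, or 5 adjusted over the list alone, SERPINA3, an acute-phase protease inhibitor, at 1.31 ± 0.28 and PIM1, a kinase, at 0.95 ± 0.22 (median 0.21, camera adjusted p = 0.102). This list passed in 5 of 23 other settings, which include array weights, the replicate block and the fit without replicate 3 with stellate cells (lowest camera adjusted p = 0.00077). Without replicate 3 with stellate cells 4 NF-kappa-B targets rose and 5 fell, and 6 STAT3 targets rose. Without replicates 1 or 3 alone 1 NF-kappa-B target fell, and 0 STAT3 targets rose without replicates 1 or 2 of either group, or 1 without replicate 3 alone. Of 20 matrix proteases and inhibitors PLAT rose at 1.34 ± 0.29, and MMP10, the collagenase MMP1 and SERPINB5 fell, the last pair at -1.86 ± 0.25 and -0.79 ± 0.17 (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.695). PLAT kept its call without replicate 3 with stellate cells, when 5 genes rose, and without replicate 2 alone, and 0 rose without any other array. Of the 3 lower calls MMP1 was the 1 left without replicate 1 with stellate cells or replicates 1 or 2 alone. In the WNT list DKK1 was the 1 gene of 14 to fall, or 2 fell adjusted over the list alone (camera adjusted p = 0.455). Among its other members BIRC5, also in the G2 and M phase list, and PPARD had values of -1.21 ± 0.34 and 0.56 ± 0.24. MMP7, CD44 and CCND1 had values of 0.08, 0.04 and -0.02, which turned sign in some settings. RELB, IL32, SERPINA3, PIM1, PLAT, MMP1, SERPINB5 and LAMB2 were named after their values were seen. The NOTCH list had 0 of 10 and the TGF-beta list 0 of 16 genes past the threshold, also 0 adjusted over the list alone (medians -0.08 and 0.20, camera adjusted p = 0.546 and 0.457). When replicate 3 with stellate cells was left out, the NOTCH and WNT lists had 2 genes lower each, and the TGF-beta list had 2 higher and 1 lower. Of the hedgehog list 0 genes were measured. Among the integrins, laminins and hemidesmosome genes 1 of 17 rose, LAMB2, or 1 rose and 1 fell adjusted over the list alone (median 0.04, camera adjusted p = 0.787), and 0 did without replicate 3 alone, while 3 were higher and 1 lower without replicate 3 with stellate cells.

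The test was limma's moderated test on normalized log2 intensities with Benjamini-Hochberg adjustment, and camera for lists. The number of arrays limits the precision, and the count of 730 probes became 189, 299 or 2758 without replicates 1, 2 or 3 with stellate cells and 277, 185 or 152 without replicates 1, 2 or 3 alone. Without background correction the log2 changes of the 52 named genes past the threshold were 41.0% to 98.4% of the values given, with a median of 77.8%, and 20 of them shrank by over 1.5 times. Of these 52 genes 35 stayed past it in all 6 fits that leave out an array. All 52 kept their direction, but the values of their groups do not overlap, so leaving out an array could not turn it. Among the 12 highest and 12 lowest genes the call was lost for BPIFB1 without any array but replicate 3 with stellate cells (highest adjusted p = 0.140) and for CDCA3 without replicate 1 with stellate cells or any array alone (0.0802). It was also lost for MMP10 without replicate 1 with stellate cells or replicates 1 or 2 alone (0.108), and for MAOB without any array alone (0.0732). TOP2A lost it without replicate 2 alone, S100A9 without replicate 3 alone, PLAAT4 without replicates 2 or 3 alone, and UHRF1 without replicate 1 with stellate cells or replicate 3 alone. RRM1 lost it without any array but replicate 3 with stellate cells (highest adjusted p = 0.191). PI3 lost it without replicate 1 with stellate cells or replicates 1 or 2 alone, CLDN3 without these or replicate 2 with stellate cells, and PROM1 without replicate 1 with stellate cells or any array alone.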

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

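Array brightness as a covariate was added after the fit without it was seen and before its own result, and after both came the member counts of the lists without single arrays. The 730 probes became 392 without the intensity trend, 3357 with array weights, 1282 at an adjusted p under 0.1, 412 at no less than a 2-fold change, 219 with a test against a 1.2-fold change and 169 with array brightness as a covariate, and leaving out 1 array gave 152 to 2758. The other planned settings gave 620 to 816 probes. The 11 lists became 1 with estimated correlations and 3 with fry, which tests whether genes move 1 way without comparing them with other genes, and 11 to 13 otherwise. With the preset correlation the lists' adjusted p ran from 1.9e-42 to 0.0421 over the alternatives. Medians past 1.5 times, beyond the fits without 1 array, were 0.11 to 0.71 for the squamous list over filters, background and scaling, 0.23 for hypoxia and 0.20 for retinoic acid with no filter on dim probes, 0.24 for hypoxia without background correction, and 0.11, 0.068 and 0.24 for the epithelial, antigen and retinoic acid lists with the mean of a gene's probes. With brightness the epithelial list was at 0.072. Same-numbered samples did not deviate together (r = -0.02, -0.03 and 0.08 across probes), and pairs with unlike numbers ran from -0.08 to 0.09. So few values cannot exclude a pairing, and the sources used here do not say what a shared number marks. With the replicate block there were 783 probes and 12 lists. Signs turned for genes not past the threshold. Leaving out 1 array gave -0.10 to 0.16 for KRT19 (negative without replicate 2 with stellate cells, -0.051, and replicate 1 alone), -0.23 to 0.032 for EPCAM (positive without replicate 2 with stellate cells), and -0.081 to 0.33 for MMP7 (negative without replicate 2 with stellate cells and replicate 1 alone, -0.023). It gave -0.054 to 0.092 for CD44 (negative without replicate 1 alone), -0.12 to 0.033 for CCND1 (positive without replicates 2 or 3, 0.032, with stellate cells and replicate 2 alone, 0.0070) and -0.19 to 0.091 for ACTB (positive without replicate 3 with stellate cells). KRT19 was at -0.0089 with brightness, CD44 at -0.0059 with median scaling, and CCND1 and ACTB at 0.069 and 0.071 with array weights. The causes were not tested, beyond the fewer samples or the stricter threshold that some settings have by construction. The slide as a block was not run since no slide is named in the sources used here, nor was a robust variance prior with camera. Signal over background limits dim genes: the 95th percentile of the signal was 8.09 to 13.2 times the background level.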

Other observations

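The tests of brightness, of the split of the arrays for lists, and of the YAP and FOXO lists were added once the changes between the groups were known but before their own results were seen, and the other tests below were chosen only after the result was seen.

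Growth factor and stress lists did not pass as lists with all arrays, but some members changed, all named after their values were seen. Of 19 EGFR ligands and ERK feedback genes EREG, the ligand epiregulin, and PHLDA1 fell, at -1.48 ± 0.25 and -0.74 ± 0.14 (log2, SE), and ERBB3, a receptor of the EGFR family, rose at 1.16 ± 0.28 (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.716). In the 18 immediate early genes the AP-1 members FOSL1 and FOSB moved apart, at -1.14 ± 0.22 and 1.17 ± 0.23 (1 and 1 adjusted over the list alone, camera adjusted p = 0.102). This list passed in 4 of 23 other settings: no filter on dim probes, without replicate 1 with stellate cells, without replicate 2 alone and with array brightness (lowest camera adjusted p = 0.0082). Of 12 p53 targets 2 rose, GDF15 at 2.01-fold and TP53INP1 at 2.30-fold (2 adjusted over the list alone, camera adjusted p = 0.503). GCLM, a subunit of the enzyme that limits glutathione synthesis, was the 1 of 21 NRF2 genes to fall, at -0.91 ± 0.16 (2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.787). ALDOC rose at 0.79 ± 0.18 and TPI1 fell at -0.62 ± 0.14 among 16 glycolysis enzymes (1 and 1 adjusted over the list alone, camera adjusted p = 0.787), and RPS7 fell at -1.07 ± 0.16 among 52 ribosomal protein genes (1 adjusted over the list alone, camera adjusted p = 0.896). Most of these calls hang on single arrays: ERBB3, FOSB, FOSL1, TP53INP1 and TPI1 lost theirs without any array but replicate 3 with stellate cells. The same holds for ALDOC, except that it also stayed without replicate 1 with stellate cells. EREG lost its call without replicates 2 or 3 alone, PHLDA1 without these or replicates 1 or 2 with stellate cells, and GCLM without replicates 2 or 3 alone or replicate 1 with stellate cells. When replicate 3 with stellate cells was left out, the EGFR list had 5 higher and 2 lower, immediate early genes 3 and 1, NRF2 genes 1 and 2, and glycolysis, p53 and ribosomal protein genes 2 and 2 each.

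Among interferon-stimulated genes the 3 that rose, named after their values were seen, were IFITM1, IFITM3 and UBE2L6, at 1.12 ± 0.22, 0.97 ± 0.22 and 0.79 ± 0.15. Calls in this list were 0 without replicate 1 with stellate cells or any array alone and with array brightness, 1 higher without replicate 2 with stellate cells, and 9 higher and 4 lower without replicate 3 with stellate cells. The respiratory chain list had 0 of 36 genes past the threshold (median -0.02, camera adjusted p = 0.503), cholesterol and fatty acid synthesis 0 of 20 (median 0.14, camera adjusted p = 0.246, or 0.0188 without replicate 2 with stellate cells), metallothioneins 0 of 7 (median -0.06, camera adjusted p = 0.979) and housekeeping genes 0 of 13 (median -0.00398, camera adjusted p = 0.457), with 2 housekeeping genes lower and 0 of the others past it adjusted over the list alone. In the fit without replicate 3 with stellate cells the respiratory chain list still had 0, cholesterol synthesis 1 higher and 2 lower, metallothioneins 1 and 1, and housekeeping genes 2 lower.

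The probes changed between the groups were set against chance, brightness and stellate cell RNA. With brightness as a covariate the changes of the called probes had a slope of 0.98 on those without it, and 0 turned sign. The median SE went from 0.21 to 0.25 and the calls from 730 to 169. Brightness correlated with the group at -0.47, and these probes had been called for the group difference. The slope therefore had little room to fall and is weak evidence against dimmer arrays as the whole cause. DCN and TAGLN were detected on 2 and 3 arrays with stellate cells and on 0 alone. The 9 stellate markers had a median change of -0.069 with an SD of 0.71, against 1.00 for the probes called higher. COL1A2 and LUM were detected on no array. These values argue against carried-over stellate cells as the whole source of those rises. A smaller carry-over stays open: S100A4, CALD1, COL6A1, ACTA2, COL1A1 and VIM were detected on all 3 arrays alone, so the median would show it poorly. COL1A1 and VIM were named after their values were seen. No sample of stellate cells alone was there to set what carry-over would add. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave 730 probes, with 0 as the highest other, and 4 splits gave at least the real 11 lists, with 19 as the highest other. The 3 others with at least 11 lists all put replicates 1 and 2 with stellate cells together against replicate 3, which points to a structure among these samples, and a response of the cancer cells stays open as the difference the design names.

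Replicate 3 with stellate cells correlated at 0.963 and 0.960 across probes with replicates 1 and 2, against 0.987 between those, and at 0.968, 0.960 and 0.967 with replicates 1, 2 and 3 alone, which correlated at 0.980 to 0.987 with each other. Its 3 ribosomal RNA genes had a median of 3.94 log2 units above the other arrays, which is consistent with more ribosomal RNA in the labelled product, and no biological explanation was tested. For 95 small RNA genes the median was 0.21, under the 0.25 of replicate 3 alone but above the -0.44 and -0.33 of replicates 1 and 2 with stellate cells. Of the 95 genes 36 were highest on this array, against 23 on replicate 3 alone. A wider gain of RNA without poly(A) tails therefore stays open. Over 2758 probes called without it, the array lay at 0.42 of the way from Capan1 alone to Capan1 with stellate cells. Replicates 1 and 2 with stellate cells, each left out in turn, lay at 1.06 and 0.98, and the arrays alone at 0.00 to 0.14. The array thus lay above those alone but nearer to them than to its own group. The arrays alone were placed over 152 to 277 probes, from fits that kept this array under its label. The placements are therefore not alike, and a Capan1 alone sample under a wrong label stays open. Stellate markers were at a median of -0.30 against the other arrays, inside the SD of 0.49 over its 9 genes, so stellate cells in that capture stay open.

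Lower DKK1, CAV1 and MMP1 beside lower genes of G2 and M phase raised hypotheses on the signals involved, whose lists share 3 YAP, 16 ERK and 6 FOXO genes with lists tested before. A list of 17 measured YAP and TEAD targets had a median change of -0.24 with 0 genes past the threshold (camera adjusted p = 0.374), and 17 ERK output genes had one of 0.034 with 0 higher and 3 lower, EREG, FOSL1 and PHLDA1, and a camera direction opposite to the median (camera adjusted p = 0.678), so neither is settled. A list of FOXO and quiescence genes had a median of 0.78, with 7 of 21 measured genes higher and 0 lower (camera adjusted p = 8.5e-09, and unadjusted p = 0.108 with an estimated correlation). MXD4, an antagonist of MYC, KLHL24 and BCL6, a transcriptional repressor, were at 1.49 ± 0.24, 1.29 ± 0.23 and 1.02 ± 0.15, and YPEL5, TSC22D3, ERBB3 and TP53INP1 also rose, all of them named after their values were seen. Of the 21 genes 18 had values above 0 and 3 below. CDKN1B, CDKN1C, RBL2 and TXNIP, also named after their values were seen, did not pass, at -0.17 ± 0.20, 0.29 ± 0.27, 0.22 ± 0.26 and -0.58 ± 0.33. A shift toward quiescence may accompany the lower mitotic genes. It stays open since the test rests on the preset correlation and on a list chosen once the changes between the groups were known.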
